A study of Homo sapiens with 6 samples.

How the data were processed

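Total RNA from 6 separate cultures of HCT-shSLBP cells, derived from the colorectal carcinoma line HCT116, was measured on 1 Affymetrix Human Transcriptome Array 2.0 per culture, with 3 cultures left untreated and 3 given doxycycline at 2 µg/ml. Per the labels' protocols, RNA was column-purified, and amplified, biotinylated sense-strand cDNA was hybridised. The time of exposure to the drug was not given in the sources used here. Groups and replicate numbers were read from the sample titles. The labels describe the cultures as independent, so the spread between arrays includes the spread between cultures, and the number of arrays limits the precision.

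The authors deposited 1 value per probe set and array, made with RMA per the submitters' processing notes, a method that subtracts background, equalises the distributions of the arrays and summarises the probes of a set. The software version, genome build and annotation were not given in the sources used here. The deposited values were read as log2 from their range of 0.485 to 14.2. The array medians lay between 4.12 and 4.17. No detection call is attached to the values. The level under which 95% of 359 olfactory receptor genes lay, 4.52, was therefore used as a yardstick for signal over background, a choice made after the data were seen. Of the genes tested, 14761 were above it.

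The table held 70523 probe sets. Through the platform's annotation, 23781 carried 1 gene symbol, 1543 carried several and 45199 were unnamed here. Older symbols were updated through RefSeq's gene table for GRCh38.p14, which changed 306. This table was used for names, gene classes and chromosomes, and no coordinates are printed because the authors' build is not known. Genes were named only from probe sets with 1 symbol, which gave 22411 genes. For 528 genes with more than 1 probe set, the probe set with the highest mean over the 6 arrays was kept. Values identical to those of another gene on every array were held by 27 genes, 3 of which fell and none of which rose or is in a gene list.

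Each gene was tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, no trend, not robust) on the log2 values with treatment as the only term. P-values were adjusted by the Benjamini-Hochberg method over all genes, and adjusted p under 0.05 is what "rose" and "fell" refer to. SLBP was also tested with an exact two-sided permutation test, which cannot give a p under 0.1 with 3 arrays against 3. Of 30 gene lists with 833 members, 699 members were measured as single genes. Lists with at least 5 measured members, and the union of the replication-dependent histone lists, were tested with limma's camera with a preset inter-gene correlation of 0.01, adjusted over the lists. Camera with an estimated correlation and fry were run beside it. No member of the list of mitochondrially encoded transcripts was measured under its symbol, so that list is not analysed here. Tables were prepared with Python 3.11.15 and pandas 2.3.3, and figures were drawn with matplotlib 3.10.9.

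The genes named from the lists and tables followed a rule fixed before the data were examined. It took SLBP, the 10 largest rises and the 10 largest falls among genes past the threshold whose higher group mean was at or above the median of all tested genes and whose groups did not overlap, and from each list the 2 members with the smallest adjusted p plus up to 2 further members with the largest changes past the threshold. Genes named outside it are said to be so. The lists, tests and most alternatives were fixed at the same time. Histone genes are near-identical copies, and most H3 and H4 probe sets carry several symbols. For this reason 69 probe sets whose symbols all belong to 1 replication-dependent histone family were also tested in a fit of all probe sets, an analysis chosen after the data were seen.

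The procedure was tested on simulated data with the means and variances of the 22411 genes and 200 genes changed by known amounts, with a further 49 genes of the DNA replication list lowered by 0.3 on the log2 scale. Of the 200, it recovered 49.3% of 67 genes changed by 0.3 on the log2 scale, 70.1% of 67 changed by 0.5 and 93.9% of 66 changed by 1. Of the 49 list genes 23 were called. Of 173 calls in all, 8 were unchanged genes. The simulated noise was drawn independently for each gene and array, without correlation between genes or differences between arrays. The share of false calls therefore holds for that setting and not for the deposited data.

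The alternatives were a repeated quantile normalization, median centring of each array, subtraction of each array's 5th percentile on the linear scale with a floor of 16, a filter on genes under the median level, eBayes with trend and robust settings, array weights, the mean of a gene's probe sets, every probe set tested on its own, the replicate number as a block, and each array left out in turn. Added after seeing the data were a fit of protein-coding genes, lists without members shared with another list, the DNA replication list without SLBP with either correlation, and the histone probe sets.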

Results

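The series compared HCT-shSLBP cells grown with and without doxycycline. HCT-shSLBP is a derivative of HCT116, a human colorectal carcinoma line, and its name refers to a short hairpin RNA against SLBP. SLBP, the stem-loop binding protein, binds the hairpin at the 3' end of replication-dependent histone mRNAs and is needed for their processing and translation. The series is described by its submitters as a study of cells depleted of histones. Gene-level signals were available for 3 untreated cultures and 3 cultures given doxycycline at 2 µg/ml. All log2 changes below are doxycycline over untreated. No doxycycline-treated culture without the hairpin is part of the comparison, so an effect of the drug and an effect of the hairpin are measured together.

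SLBP was lower in every treated culture. Its log2 signal was 8.09, 8.04 and 8.08 in the untreated cultures and 7.38, 7.19 and 7.32 in the treated ones, or 8.07 ± 0.029 against 7.30 ± 0.098 (SD, n = 3 per group). The log2 change was -0.77 (SE 0.055, limma adjusted p = 0.00322), which left 58.6% of the untreated signal. The exact permutation test gave p = 0.1, the smallest that 3 arrays against 3 allow.

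Among genes whose higher group mean was at or above the median level of all tested genes, the largest falls besides SLBP were in the histone genes H2BC14 (-1.23), H2BC11 (-0.84) and H2BC17 (-0.65), in GINS2 (-0.75), a subunit of the replicative helicase, and in CCNE2 (-0.66), the cyclin E2 that acts at entry into S phase. FAM111B (-0.75), NCOA5 (-0.73), a nuclear receptor coregulator, SSX1 (-0.69), a cancer-testis gene, and MYO5C (-0.65), a class V myosin, completed these falls. The largest rises among these genes were in EMP1 (0.92), an epithelial membrane protein, MALAT1 (0.91), a nuclear long noncoding RNA, SAT1 (0.87), which acetylates polyamines, and MIR221 (0.82), a microRNA gene. They were followed by the keratin-associated proteins KRTAP2-2 (0.80) and KRTAP2-1 (0.75), ZFP36 (0.75), which promotes decay of AU-rich mRNAs, SNORD93 (0.66), a small nucleolar RNA, IRS2 (0.64), an insulin receptor substrate, and FKBP14 (0.63), a prolyl isomerase of the endoplasmic reticulum. The rule that picked these genes required all 3 treated arrays on the same side of all 3 untreated arrays and a limma adjusted p under 0.05. Their SE lay between 0.042 and 0.134, and their limma adjusted p was at most 0.0379.

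**Figure D1:**
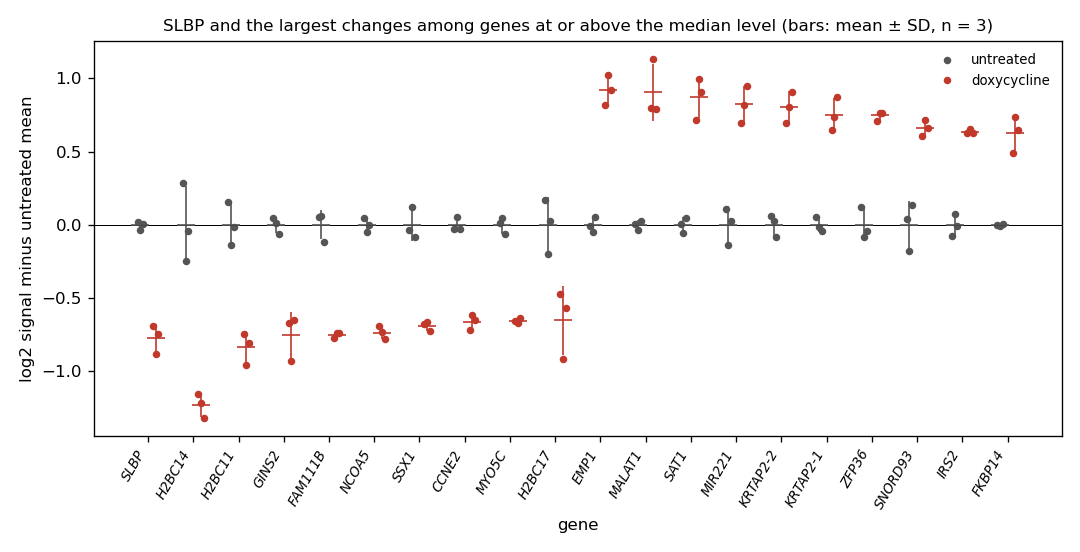
Log2 signal of SLBP, the genes with the largest falls and the genes with the largest rises on each array, among genes whose higher group mean was at or above the median level, minus the gene's mean in untreated cultures. Points are arrays, and horizontal marks with bars are mean ± SD (n = 3). The mean of H2BC11 was 8.58 in untreated and 7.74 in treated cultures, and that of EMP1 was 7.92 and 8.85. The rule for picking the genes required that the groups do not overlap.

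Of 22411 genes tested, 656 rose and 732 fell, 6.19% in all. Most changes were small, with a median absolute log2 change of 0.27 among the changed genes. Only 2 genes rose at least 2-fold, the microRNA genes MIR29A (1.56, SE 0.110) and MIR21 (1.12, SE 0.066), and 2 fell at least 2-fold, H2BC14 and the microRNA gene MIR4521 (-1.03, SE 0.087). These 3 microRNA genes lay under the median level of all genes and were named after their values were seen. The groups did not overlap in 6547 genes, 29.2% of those tested, where chance gives 10%. The numbers of calls depended on single arrays: without doxycycline replicate 3, 63 genes rose and 69 fell, without untreated replicate 3 the numbers were 107 and 99, without untreated replicate 1 they were 176 and 164, without untreated replicate 2 they were 201 and 234, and without doxycycline replicate 2 they were 300 and 283. These fits have fewer arrays and hence less power. Of 83 named genes with a call, 48 lost it without doxycycline replicate 3, 41 without untreated replicate 3, 34 without untreated replicate 1, 27 without untreated replicate 2, 24 without doxycycline replicate 2 and 17 without doxycycline replicate 1. With array weights 1511 rose and 1714 fell, with dim genes left out 1156 and 1413, and with background subtraction 1025 and 1137.

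Replication-dependent histone genes, whose mRNAs SLBP binds, were lower as a group. Of 33 measured as single genes, 11 fell, none rose and 28 had lower means in treated cells, with a median log2 change of -0.24. Only 18 of the 33 lay above the olfactory receptor level, among them 6 of 9 in the H2A list and 7 of 15 in the H2B list. Adjusted over the list alone, 19 fell and 1 rose. Camera gave adjusted p = 6.61e-08 with the preset correlation and adjusted p = 0.194 with an estimated correlation. In the H2B list, 5 of 15 fell, led by H2BC14 and H2BC11 and including H2BC12 (-0.41, SE 0.069), with 10 lower and 1 higher when adjusted over the list alone (camera adjusted p = 0.000171, and adjusted p = 0.264 with an estimated correlation). In the H2A list, 4 of 9 fell, H2AC12 (-0.55), H2AC21 (-0.52), H2AC13 (-0.43) and H2AC14 (-0.48), the last from a signal of 2.94, under the olfactory receptor level, and 7 were lower when adjusted over the list alone (camera adjusted p = 6.48e-05, and adjusted p = 0.194 with an estimated correlation). Of 6 linker histone H1 genes, H1-4 fell (-0.43, SE 0.081) and H1-2 did not pass the test (-0.23, adjusted p = 0.0859). Adjusted over the list alone 2 of the 6 were lower, and the list as a whole did not pass (camera adjusted p = 0.223). H4C3 fell (-0.24) while H4C7 (-0.23, adjusted p = 0.33, from a signal of 2.13) and the single measured H3 gene, H3-4 (-0.11, adjusted p = 0.209), did not pass. H2BC17 and H1-4 lost their calls whenever an array other than doxycycline replicate 1 was left out, with adjusted p of up to 0.119 and 0.0996.

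Near-identical histone genes can share probes, so values of single members are uncertain. Over 69 probe sets of these families, those that carry several symbols included, 62 were lower in treated cells and the median log2 change was -0.30. The medians were -0.47 for 16 H2A probe sets, -0.34 for 19 H2B, -0.47 for 13 H3, -0.23 for 15 H4 and -0.065 for 6 H1. All 13 H3 probe sets were lower, but none passed limma's test after adjustment over all probe sets. Most of them carry several symbols, so they may not be independent. In this fit of every probe set, 7 of the 69 fell and none rose after adjustment over all 70523, and camera gave p = 1.64e-22 with the preset correlation and p = 0.0448 with an estimated correlation for the 69 together. Of the histone genes named above as fallen, H2BC14, H2BC11, H2AC12 and H2AC14 also passed in this fit. H2BC12, H2BC17, H2AC21, H2AC13, H1-4 and H4C3 did not, with limma adjusted p of 0.0789 to 0.117. The fit of these probe sets was chosen after the data were seen.

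**Figure D2:**
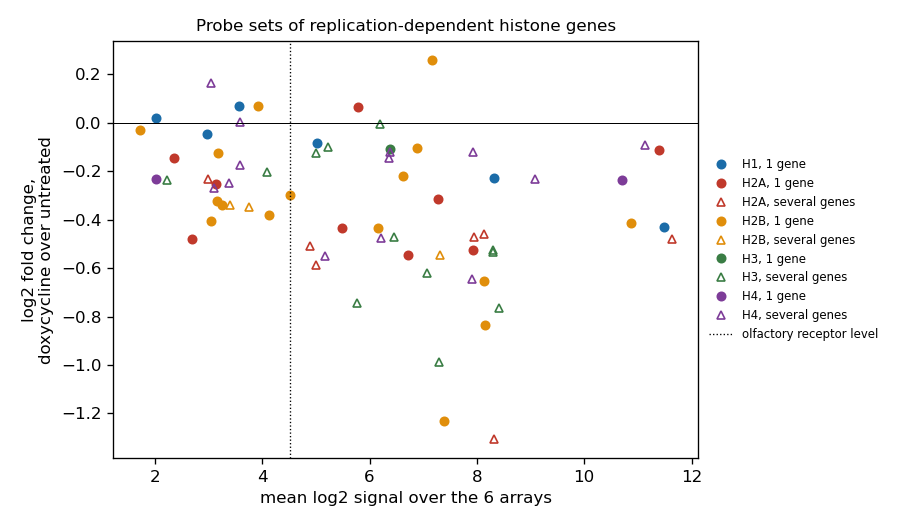
Log2 change of each of the 69 probe sets of replication-dependent histone genes against its mean log2 signal over the 6 arrays. Colours are histone families, filled circles are probe sets annotated to 1 gene, open triangles those annotated to several, and the dotted line is the olfactory receptor level of 4.52. Of 44 probe sets above that level, 42 lay below 0, with a median of -0.45.

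Other histone-related genes also moved. Of 8 replacement variants, which are made outside S phase too, H2AZ2 (-0.34, SE 0.036) and H2AX (-0.41, SE 0.090) fell, and 5 were lower when adjusted over the list alone (camera adjusted p = 0.0106, and adjusted p = 0.264 with an estimated correlation). The call of this list was lost without doxycycline replicate 1 (adjusted p = 0.0542), and H2AX lost its call in each of the 6 fits that left out an array. Of 25 histone chaperones, 8 fell and 1 rose, and 16 were lower and 2 higher when adjusted over the list alone. The falls included both large subunits of chromatin assembly factor 1, CHAF1A (-0.42, SE 0.048) and CHAF1B (-0.42, SE 0.039), ASF1B (-0.39, SE 0.071) and MCM2 (-0.58, SE 0.083), which is also a helicase subunit in the DNA replication list. Camera gave adjusted p = 6.80e-06 for the chaperones, and adjusted p = 0.0529 with an estimated correlation. Of 21 genes of histone mRNA 3' end processing, 5 fell and none rose, among them NCBP1 (-0.30), SRRT (-0.34), CSTF2T (-0.33) and CASP8AP2 (-0.26), and 7 were lower and 2 higher when adjusted over the list alone. Camera gave adjusted p = 0.0447 for this list, and adjusted p = 0.194 with an estimated correlation. Its call was also lost with background subtraction, without dim genes, with array weights, with the replicate number as a block, without untreated replicate 2 and without doxycycline replicate 1.

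Genes of DNA replication and S phase were the most uniformly lower group. All 49 measured members had lower means in treated cells, 39 fell, and 45 were lower when adjusted over the list alone, with a median log2 change of -0.36. MCM6 (-0.51, SE 0.034), a subunit of the replicative helicase, CCNE2 and GINS2 were among them, and SLBP itself is a member. Camera gave adjusted p = 9.99e-35 with the preset correlation and adjusted p = 0.0529 with an estimated correlation. Without SLBP, a variant added after seeing the data, the mean log2 change was -0.38, with camera adjusted p = 8.76e-34 with the preset correlation and adjusted p = 0.0529 with an estimated correlation. Of 39 genes of mitosis, 38 had lower means, 9 fell and none rose, and 24 were lower when adjusted over the list alone. CCNB1 (-0.38, SE 0.037), the mitotic cyclin B1, the kinases AURKA (-0.34, SE 0.041) and PLK1 (-0.29, SE 0.048), and GTSE1 (-0.33, SE 0.051) were among those that fell. The median was -0.17, and camera gave adjusted p = 1.73e-11 with the preset correlation and adjusted p = 0.0529 with an estimated correlation.

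**Figure D3:**
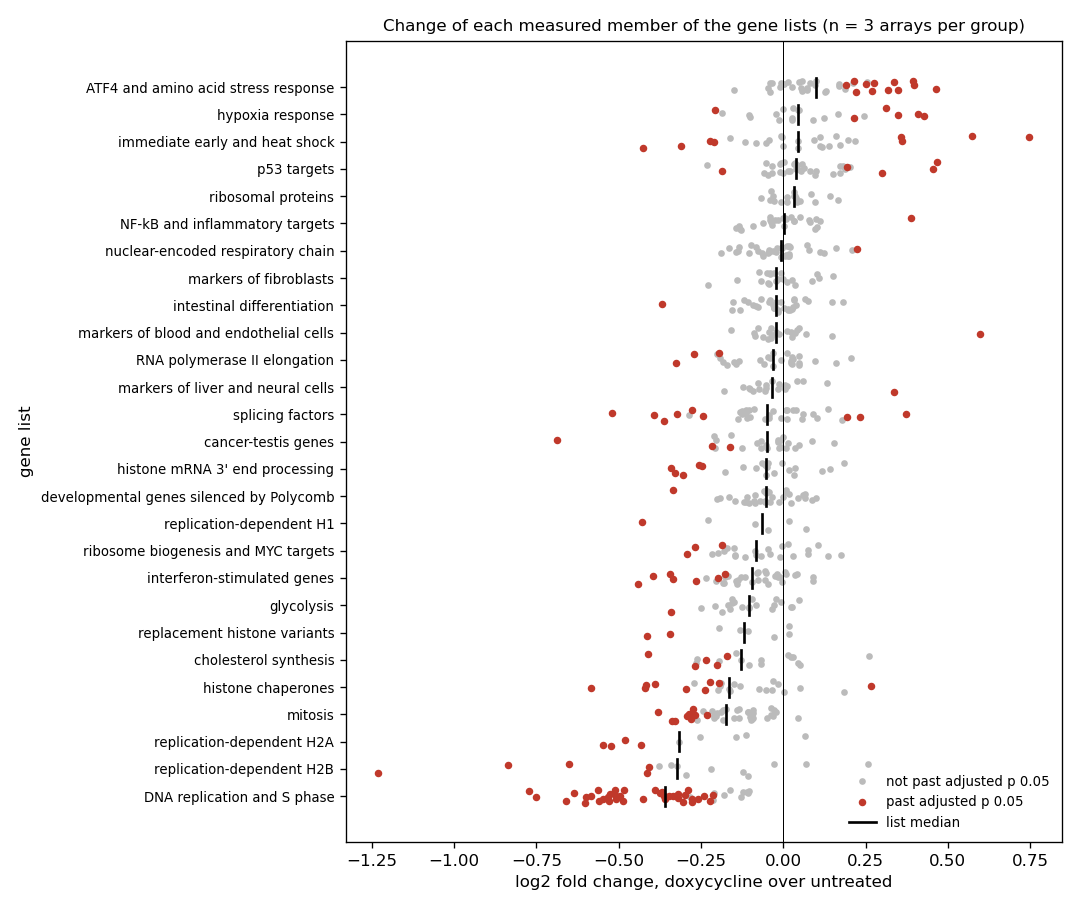
Log2 change of each measured member of the gene lists with at least 5 measured members, lists ordered by their median. Points are genes, red where the limma adjusted p passed 0.05, and black bars are list medians. The medians run from -0.36 for DNA replication and S phase to 0.10 for the ATF4 list.

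Targets of ATF4, the transcription factor of the amino acid stress response, were higher. Of 39, 12 rose and none fell, and 18 were higher when adjusted over the list alone. ASNS (0.40, SE 0.033), asparagine synthetase, DDIT3 (0.46, SE 0.063), a stress-induced transcription factor, CTH (0.39, SE 0.062), which makes cysteine, and DDIT4 (0.35, SE 0.068), an inhibitor of mTORC1, were among them. The median was 0.10, and camera gave adjusted p = 4.77e-10 with the preset correlation and adjusted p = 0.0543 with an estimated correlation. Of 36 p53 targets, 4 rose and 1 fell, and 8 were higher and 2 lower when adjusted over the list alone. The rises were in PLK2 (0.46), PLK3 (0.30), GDF15 (0.47), a secreted stress cytokine, and ZMAT3 (0.19). The median was 0.040, with camera adjusted p = 0.000421 and adjusted p = 0.0726 with an estimated correlation. GDF15 lost its call without untreated replicate 1, 2 or 3 and without doxycycline replicate 1 or 3. In the hypoxia list, 5 of 21 rose and 1 fell, and 7 were higher and 1 lower when adjusted over the list alone. NDRG1 (0.43), BHLHE40 (0.41), DDIT4 and MXI1 (0.31) rose (camera adjusted p = 0.00186, and adjusted p = 0.0833 with an estimated correlation).

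Immediate early and heat shock genes went both ways. Of 27, 4 rose and 4 fell, and 8 were higher and 4 lower when adjusted over the list alone. ZFP36, DUSP5 (0.57), a MAP kinase phosphatase, and FOSL1 (0.36), an AP-1 subunit, rose, while the chaperone gene HSPA1A (-0.42, SE 0.091) fell. Camera called the list higher with adjusted p = 0.0254, and adjusted p was 0.536 with an estimated correlation. The call was also lost with fry (adjusted p = 0.160), with background subtraction, without dim genes, without untreated replicate 3 and without doxycycline replicate 3.

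Interferon-stimulated genes were lower, with 7 of 37 fallen and none risen, and 11 lower when adjusted over the list alone. SAMD9 (-0.44), IFI27 (-0.40), ISG15 (-0.34) and IFI6 (-0.34) fell (camera adjusted p = 0.000198, and adjusted p = 0.0726 with an estimated correlation). In cholesterol synthesis, 5 of 19 fell, among them ACAT2 (-0.41), EBP (-0.27), FDPS (-0.24) and MVK (-0.20), with 10 lower and 1 higher when adjusted over the list alone (camera adjusted p = 0.00199, and adjusted p = 0.175 with an estimated correlation). In glycolysis only TPI1 (-0.34), triosephosphate isomerase, fell of 21 members, and PGAM1 did not pass (-0.25, adjusted p = 0.0605). Adjusted over the list alone, 10 were lower (camera adjusted p = 0.000421, and adjusted p = 0.384 with an estimated correlation).

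The following lists did not pass camera with the preset correlation. Of 36 splicing factors, 6 fell and 3 rose (8 and 4 adjusted over the list alone), with HNRNPM (-0.52), SRSF3 (-0.36) and U2AF2 (-0.39) lower and MBNL2 (0.37) higher (camera adjusted p = 0.115). Of 29 genes of RNA polymerase II elongation, 3 fell, ELOA (-0.27), HEXIM1 (-0.33) and SUPT6H (-0.20), with 6 lower and 2 higher adjusted over the list alone (camera adjusted p = 0.188). Of 25 genes of ribosome biogenesis, MRTO4 (-0.29), PES1 (-0.27) and ODC1 (-0.19) fell, with 7 lower and 1 higher adjusted over the list alone (camera adjusted p = 0.0575). None of 18 ribosomal protein genes passed limma's test at an adjusted p, over all genes or over the list alone, and RPS12 (0.14, adjusted p = 0.0766) and RPS27 (0.17, adjusted p = 0.101) had the smallest adjusted p, with 3 of the 18 at an unadjusted p under 0.05 (camera adjusted p = 0.0575). In the nuclear-encoded respiratory chain UQCRC2 (0.22) rose of 35, and 1 was higher adjusted over the list alone, while NDUFB10 did not pass (-0.19, adjusted p = 0.0805, camera adjusted p = 1.00).

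Of 33 intestinal differentiation genes AXIN2 (-0.37), a feedback inhibitor of WNT signalling, fell and KRT20 (-0.16, adjusted p = 0.073) did not pass (camera adjusted p = 0.771). Among 25 cancer-testis genes, SSX1, MAGEB2 (-0.22) and SYCP3 (-0.16, from a signal of 1.99) fell, with 6 lower adjusted over the list alone. The mean log2 change of this list was -0.080 (camera adjusted p = 0.0527, and adjusted p = 0.295 with an estimated correlation), but -0.24 with background subtraction (camera adjusted p = 0.00068) and -0.29 without dim genes (camera adjusted p = 0.0024), and fry called it lower (adjusted p = 0.0185). The fits with background subtraction and without dim genes dropped genes of low signal. Only 7 of the 25 members lay above the olfactory receptor level, so the means in those fits cover fewer members. Over all alternatives in which lists were tested, the adjusted p of the cancer-testis list by camera or fry ranged from 0.00068 to 0.295. The list of developmental genes silenced by Polycomb is named for a state that was not measured in these cells. Of its 33 measured members, 25 lay above the olfactory receptor level. LHX2 (-0.34) fell and HOXD12 (-0.20, limma adjusted p = 0.11) did not pass (camera adjusted p = 0.142). Of 27 inflammatory targets of NF-kB, IL18 (0.39) rose and NFKBIA (-0.13, adjusted p = 0.0779) did not pass (camera adjusted p = 0.732). The counts adjusted over the list alone were the same for these intestinal, Polycomb and NF-kB lists. Markers of cells foreign to the culture gave camera adjusted p of 0.961 for fibroblasts, 0.672 for blood and endothelium, and 0.771 for liver and neural cells, with 21 members measured in each. For blood and endothelium the median was -0.024 while the mean was 0.014. CD68 (0.60, SE 0.038), a lysosomal protein of macrophages and other cells, and GAD1 (0.34, SE 0.040), glutamate decarboxylase, rose as the single members of their lists, also when adjusted over the list alone. HBB (0.15, adjusted p = 0.222), APOC3 (-0.18, adjusted p = 0.0766), TWIST1 (-0.14, adjusted p = 0.109) and S100A4 (-0.23, adjusted p = 0.113) did not pass. No fibroblast marker passed limma's test at an adjusted p, and 4 of the 21 had an unadjusted p under 0.05.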

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

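The tests on the histone probe sets and on a direct action of doxycycline were chosen after their results were seen, and the tests for drift with brightness and for other splits of the arrays were written before. Probe sets outside the gene-level comparison also carried a difference. In a fit of all 70523 probe sets, 103 of 45199 unnamed probe sets were higher with doxycycline and 81 lower, and 17 of 1543 probe sets with several symbols were higher and 7 lower.

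Other splits of the 6 arrays into 3 and 3 called no gene at adjusted p with limma in the other 9 of 10 splits, with 528 to 1118 genes at an unadjusted p under 0.05, against 1388 called genes and 5063 at an unadjusted p for the real split. Only the real split, 1 of 10, called as many genes, and the same held for genes changed at least 2-fold, 4 against a highest other number of 0. For gene lists called by camera with the preset correlation, the real split gave 15 and the highest other split 14, and again 1 of 10 splits gave as many. With 10 splits the share cannot be under 0.1.

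The replication-dependent histone probe sets were lower, which sets an explanation by shared probes against biological ones. The fall was not limited to probe sets annotated to several genes: 19 annotated to 1 gene and above the olfactory receptor level had a median of -0.32, below all medians of 10000 random gene sets of matched brightness. Cross-hybridisation within such probe sets remains open, because probe sequences were not analysed here. A smaller share of cells in S phase is a candidate explanation: 48 genes of the DNA replication list other than SLBP, whose mRNAs lack the histone stem-loop, had a median of -0.35, against -0.45 for the 44 histone probe sets above that level. Loss of SLBP itself stays open too, untested, as the drug and the hairpin come together and cell cycle phases were not measured.

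The ATF4 list was higher in camera with the preset correlation, but did not pass with an estimated correlation (adjusted p = 0.0543). A drift with brightness in the deposited values is argued against. Genes of matched brightness had a median of -0.016, and the list's median of 0.10 lay above all 10000 matched random sets. RMA equalises the distributions of the arrays, so little such drift could remain, and the test does not bear on other technical causes. A direct action of doxycycline, which inhibits mitochondrial translation, and loss of SLBP cannot be told apart, since no treated culture without the hairpin was compared. The median of -0.0053 over the nuclear-encoded respiratory chain genes, which went both ways, does not decide it.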

How the results depend on the processing

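The fit of protein-coding genes, lists without shared members, DNA replication without SLBP and the histone probe sets were chosen after the data were seen. The fits of every probe set and of protein-coding genes were compared by counts only. They are left out of the comparisons of SLBP, the gene lists and the named genes, apart from the histone probe sets. SLBP kept its fall and its call in every alternative in which it was assessed, with log2 changes of -0.81 to -0.72 and adjusted p of 0.000183 to 0.0425. The replication-dependent histones, DNA replication, mitosis, ATF4, chaperone, p53 and hypoxia lists kept direction and call in all alternatives assessed except camera with an estimated correlation. Of 1342 comparisons of 97 named genes with an alternative, 1089 kept direction and side of the threshold, 222 lost the call, 31 gained it and none changed sign. Of 83 called named genes, 48 lost the call without doxycycline replicate 3. Signal over background limits the dim genes: subtraction left 6547 genes at the floor.

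Genes higher and lower were 1025 and 1137 with background subtraction, 1156 and 1413 without dim genes, 1511 and 1714 with array weights, and 186 and 158 probe sets when each of 70523 was tested. Protein-coding genes alone gave 909 and 1180. With arrays left out in turn, 63 to 561 were higher and 69 to 537 lower. At least 2-fold lower were 1 gene without dim genes, 1 with array weights, 1 among protein-coding genes, 4 among all probe sets and 1 to 2 with arrays left out. At least 2-fold higher were 10 probe sets, and 0 genes by limma without dim genes or among protein-coding genes, also 0 at an unadjusted p under 0.05, because MIR29A and MIR21 are in neither fit.

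With the replicate number as a block, 157 genes were higher and 174 lower, and 25 of the 83 called named genes lost the call. Over all 22411 genes, same-numbered arrays did not deviate together from their group means (correlations 0.0301, -0.000557 and -0.0159). These correlations gave no sign that the numbers pair the cultures. They run over all genes, dim ones included, and so cannot exclude a shared replicate effect in a part of the genes. The block ended the call of the 3' end processing list (mean -0.078) and called ribosome biogenesis lower (-0.072).

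With an estimated correlation, camera called 0 of 28 lists, 8 at an unadjusted p under 0.05, against 15 with the preset one and 17 with fry, and without SLBP the DNA replication list (-0.38) lost its call likewise. The 15 lists that lost the call had mean log2 changes of -0.31 (H2A), -0.34 (H2B), -0.27 (all replication-dependent histones), -0.15 (replacement variants), -0.078 (3' end processing), -0.16 (chaperones), 0.071 (p53), -0.38 (DNA replication), -0.17 (mitosis), -0.12 (interferon), 0.14 (ATF4), -0.11 (glycolysis), 0.090 (hypoxia), -0.11 (cholesterol) and 0.067 (immediate early). Fry called splicing factors (-0.061), ribosome biogenesis (-0.072) and cancer-testis genes (-0.080) lower and lost immediate early genes (0.067). The 3' end processing list lost its call with background subtraction (-0.079), without dim genes (-0.078) and with array weights (-0.070), and immediate early genes with background subtraction (0.069) and without dim genes (0.062). Cancer-testis genes were called lower with median centring (-0.071), array weights (-0.092) and mean probe sets (-0.081). They were also called lower with background subtraction (-0.24) and without dim genes (-0.29), where the means cover fewer members. Ribosomal proteins were called higher after quantile normalization (0.043) and centring (0.039), and ribosome biogenesis lower after centring (-0.063). The respiratory chain mean turned to 0.0028 after quantile normalization and that of liver and neural markers to 0.023 with background subtraction, neither called.

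With arrays left out in turn, calls were lost in some fits by replacement variants (means -0.18 to -0.12), 3' end processing (-0.083 to -0.071) and immediate early genes (0.042 to 0.091). Calls were gained in some by ribosomal proteins (0.012 to 0.042), cancer-testis genes (-0.098 to -0.071), ribosome biogenesis (-0.078 to -0.064), splicing factors (-0.066 to -0.054) and RNA polymerase II elongation (-0.062 to -0.040). The means of uncalled lists that crossed 0 were -0.026 to 0.0019 (respiratory chain), -0.0043 to 0.021 (NF-kB) and -0.0045 to 0.025 (blood and endothelium). The cause of these changes was not tested.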

Other observations

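The families below were picked because some of their members stood out, so all their tests were chosen after the data were seen. Their p-values come from the same arrays that led to the choice, and the adjustment over 7 families does not cover it. These p-values therefore describe the families and cannot be ranked against those of the lists fixed beforehand. The test of the proteasome for drift with brightness was written before its own result was seen. Subunits of the proteasome, which degrades ubiquitinated proteins, were lower almost throughout: of 36 genes, 20 fell, none rose, and 35 had lower means. PSMC3 (-0.48, SE 0.047), PSMB6 (-0.37, SE 0.063) and PSMC4 (-0.35, SE 0.054) had the largest falls, and the median was -0.19 (camera adjusted p = 1.58e-14 over 7 families, and adjusted p = 0.0116 with an estimated correlation). Of 28 genes of the COPII and COPI coats and the COG tethering complex, which act in transport between endoplasmic reticulum and Golgi, 14 rose, none fell and 14 did not pass, 4 with lower means. The rises were led by SEC24D (0.58), COG6 (0.55) and SEC24A (0.49), and the median of the 28 was 0.22 (camera adjusted p = 1.62e-14, and adjusted p = 0.0112 with an estimated correlation). Neither family shares a member with the lists fixed beforehand.

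Of 16 circadian clock genes, 6 rose, NR1D1 (0.61), DBP (0.51), BHLHE40 (0.41), PER1 (0.40), BHLHE41 (0.27) and NR1D2 (0.25), while CLOCK (0.018) and BMAL1 (-0.077) did not pass (camera adjusted p = 2.38e-05, and adjusted p = 0.0178 with an estimated correlation). BHLHE40 is also in the hypoxia list. Among 12 feedback targets of WNT signalling, DKK4 (-0.49), AXIN2 (-0.37) and RNF43 (-0.27) fell and none rose (camera adjusted p = 0.0013, and adjusted p = 0.217 with an estimated correlation). Of 29 keratin-associated protein genes on chromosome 17, near-identical neighbours that can share probes, 6 rose and none fell (camera adjusted p = 1.70e-06, and adjusted p = 0.0116 with an estimated correlation). In the family of the U6 small nuclear RNA and its pseudogenes, 7 of 73 members fell and 50 had lower means. RNU6-1, RNU6-11P and RNU6-37P hold identical values on every array, so the 7 calls stand for 5 distinct rows of values. RNU6-33P (-0.404) and RNU6-36P (-0.390) lie close to that trio (-0.411), so the 5 rows may not be independent. In the family of U7, the small nuclear RNA of histone mRNA processing, and its pseudogenes, 4 of 68 members rose and 43 had higher means. The 4 that rose, RNU7-50P, RNU7-57P, RNU7-67P and RNU7-7P, are all pseudogenes. All 68 lay under the olfactory receptor level. Camera with the preset correlation gave adjusted p = 0.000727 for the U6 family and adjusted p = 0.00186 for the U7 family. Both families had adjusted p = 0.295 with an estimated correlation.

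For the proteasome, a drift with brightness in the deposited values is argued against, since genes of matched brightness had a median of -0.0165, far smaller than the family's -0.19. Here too, RMA leaves little room for such a drift, and the test does not bear on other technical causes. Whether a smaller share of dividing cells accounts for the fall was not decided. The prediction for that explanation was a proteasome median above that of the mitosis list by more than the spread of their difference. The proteasome median differed from that of the mitosis list by -0.0202, so the predicted difference was not seen. The 95% bootstrap interval over genes was -0.126 to 0.048 and reaches both signs, so that the test does not separate the explanations. Genes are not independent replicates, and the interval covers only the spread between them. Loss of SLBP and the drug itself stay open as untested.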
